A study of Mus musculus with 2 samples.

How the data were processed

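Polyadenylated RNA of cultured, immortal mouse embryonic fibroblasts was captured with oligo-dT primers and sequenced after Smart-seq2 library preparation, per the labels' protocols. The cells were hybrids of the strains C57BL/6N (B6 below) and PWK/PhJ (PWK below). There were 2 libraries, 1 from a line whose inactive X chromosome (Xi) is the B6 copy (B6-Xi) and 1 from a line whose Xi is the PWK copy (PWK-Xi), and the group of each library was taken from its title. The submitters' processing notes name Trim Galore 0.6.4, HISAT2 2.2.0, StringTie 2.1.1 and the genome build mm9. How reads were assigned to a strain is not given in the sources used here.

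The authors deposited, for each library, FPKM values (fragments scaled by transcript length and library size) of 22711 genes, with 1 column for the B6 allele and 1 for the PWK allele per the file headers. These are normalized values and not counts, so the read depth behind a gene is unknown and no counting interval was given. The shares of the alleles often stood in simple ratios. Among genes with at least 1 FPKM, 47.1% in B6-Xi and 12.8% in PWK-Xi had a B6 share equal, within 0.001 percentage points, to a fraction with a denominator of at most 10, so shares moved in coarser steps in B6-Xi. Values of exactly 0 included genes that all cells use (Vim, B2m and Ppia in both files), so such genes are only said to be listed at 0, and no fold against them is printed. Through the pseudocount they do enter the counts of genes past 4-fold and the ranking by difference, so both are also given for genes above 0 in both lines.

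The share of an allele was its FPKM divided by the sum of both alleles, with no pseudocount. The Xi share is the share of the strain whose X is inactive in that line, and the B6 share was used for autosomes. X-linked shares and chromosome medians used genes with a summed FPKM of at least 1 in both lines, and counts of single autosomal and imprinted genes used at least 5. A gene counted as expressed from the Xi at an Xi share of at least 10% in both lines. Expression differences of genes and gene lists were log2((PWK-Xi + 1)/(B6-Xi + 1)) of the summed allelic FPKM, for genes with at least 5 FPKM in either line. On this scale the change of low genes is understated. Differences of chromosomes, their parts and blocks were log2(PWK-Xi/B6-Xi) with no pseudocount. They used genes above 0 in both lines whose mean over the lines was at least 5 FPKM. With 1 library per group there was no replicate check, no test between conditions and no p-value. The percentile of a list's median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries only.

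Chromosomes and gene order came from GENCODE and RefSeq annotations of a later mouse assembly than mm9. Symbols matched for 21631 genes by the GENCODE name, 196 by the RefSeq symbol and 789 by a RefSeq synonym, and 95 stayed unmatched. No coordinates of either build were used. Genome-ordered B6 shares were also read as medians of non-overlapping blocks of 20 consecutive genes, compared with 1000 shuffles of the gene order. A chromosome was called skewed where its median B6 share lay more than 5 percentage points from the autosomal median of the same line; this rule, the blocks and the chromosome parts were chosen after the data were seen.

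The gene lists, the thresholds and the rule for named genes were fixed before the data were examined. Named were the measured members of the lists for the X-inactivation centre, for loci of Xi architecture and for known escape genes, X-linked genes at 10% or more, the X-linked and autosomal genes with the largest share differences (5 per direction), the 5 most abundant known silenced genes, autosomal genes from the same strain in both lines (5 per strain), imprinted genes, the 15 genes per direction with the largest difference between the lines among those with at least 20 FPKM, and the most abundant members of each list. Genes outside the rule are said to be chosen after their values were seen. Lists also covered housekeeping, Y-linked, fibroblast and matrix, contractile, p53 axis, cell cycle, interferon response, cholesterol synthesis, Hox, epithelial, endothelial, immune, pluripotency, muscle, adipocyte and neural genes. Added later, before their values were seen, were lists for embryonic stem cells, oocytes, trophoblast and primitive endoderm. Jpx, Ftx, Firre, Hmgcs1 and Sc4mol were not analysed here.

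Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data drawn on the real genes. Of genes changed 8-fold, 94.8% of 193 were called at 4-fold, and 0% of 4538 unchanged genes were. All of the simulated X-linked genes with an Xi share of 30% (9 genes) or 50% (10 genes) were recovered at 10% in both lines, as were 50% of 10 genes simulated at 15%, and 0% of 268 silent genes. Both values of 0% followed from the construction. Silent genes were given no reads from the Xi, and unchanged genes a spread far below 4-fold. The simulation also assumed a read depth and held no expressed genes listed at 0 in 1 line only, so it says nothing on false calls in the real data. Alternatives varied the minimum FPKM, the pseudocount, the Xi threshold, the scaling of alleles and libraries, and the use of pooled FPKM in place of the median gene. A result was taken as unchanged where a share moved by less than 5 points, a log2 value by less than 0.5, or a count by at most 1.5 times.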

Results

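Allele-resolved RNA-seq was available from 2 lines of immortal mouse embryonic fibroblasts, both B6 and PWK hybrids, in which the inactive X chromosome was of known and opposite strain. In B6-Xi the B6 copy is inactive, and in PWK-Xi the PWK copy. There was 1 library per line and no replicate, so each value below describes a single library. In B6-Xi 10127 of the 22711 listed genes were above 0 and 8100 had at least 1 FPKM; in PWK-Xi these numbers were 12907 and 9040. The summed FPKM of the B6 and PWK alleles were 140658 and 144739 in B6-Xi, and 138131 and 118065 in PWK-Xi. Read depth was unknown. The 10 most abundant genes held 18.4% of the summed FPKM in B6-Xi and 10.9% in PWK-Xi. Ddx3y, Eif2s3y, Kdm5d and Uty, all Y-linked, were listed at 0 in both lines.

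The first comparison asked how completely the inactive X was silent in each line. X-linked expression came almost entirely from the active X in both. Among 241 X-linked genes with at least 1 FPKM in both lines, the median Xi share was 0% in B6-Xi and 0% in PWK-Xi. The Xi allele was at exactly 0 for 227 genes in B6-Xi (94.2%) and for 199 genes in PWK-Xi (82.6%), and 231 and 234 genes lay under 10%. Shares moved in coarser steps in B6-Xi, so its higher count at exactly 0 does not show a more silent Xi. Autosomal genes measured the same way had a median share of 50% for B6 in B6-Xi and 47.3% for PWK in PWK-Xi over 7435 genes, of which 8.68% and 1.48% lay under 10%. The 8.68% includes 223 genes of chromosome 12 and a part of chromosome 4, both described below. The X-linked median was below all 10000 random autosomal lists in both lines. Taken over the summed FPKM instead of the median gene, the Xi share was 8.93% in B6-Xi and 1.18% in PWK-Xi. Rps4x alone, a ribosomal protein gene, made most of the first value: without it the pooled Xi share was 1.11% in B6-Xi and 1.34% in PWK-Xi. Both values still include Xist, a transcript of the Xi itself, with 26.7 and 44.4 FPKM from the Xi.

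Known silenced genes were read from a fixed list. Of its 28 measured members, 27 had an Xi share under 10% in both lines, and the highest of these was 2.68% (Bcap31 in PWK-Xi). Lamp2, a lysosomal membrane protein gene, had 90.2 FPKM in B6-Xi and 119.9 FPKM in PWK-Xi, all from the active X. The same held for Timp1, a metalloproteinase inhibitor gene (202.3 and 233.2 FPKM), for Plp2 (145.1 and 108.1 FPKM) and for the RNA-binding protein gene Rbm3 (134.7 and 85.9 FPKM). The exception was Rps4x, with an Xi share of 35.5% of 2077 FPKM in B6-Xi against 0.018% of 893 FPKM in PWK-Xi. Ribosomal protein genes have many processed copies in the genome, and the reads of such copies could not be separated here, so this value is uncertain.

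The second comparison asked which genes were expressed from the inactive X whichever strain it carried. 6 genes had an Xi share of at least 10% in both lines. Xist, the non-coding RNA that coats the inactive X, came from the Xi at 99.5% of 26.8 FPKM in B6-Xi and 97.2% of 45.7 FPKM in PWK-Xi. The other 5 were all members of the fixed list of known escape genes. Pbdc1 had Xi shares of 58.3% and 35.9% in B6-Xi and PWK-Xi. For Kdm5c, a histone H3 lysine demethylase gene, they were 65.6% and 23.9%. Eif2s3x, a translation initiation factor gene, had 25% and 38.7%. The RNA helicase gene Ddx3x had 29.6% and 14.7%. Kdm6a, another histone demethylase gene, had 10.0%, exactly at the threshold, and 23.1%. Kdm5c and Kdm6a lay between 1.92 and 3.73 FPKM, and with a minimum of 5 FPKM 4 genes were left. At no gene of the 5 did the Xi allele exceed the active allele in both lines. For Kdm5c and Pbdc1 the B6 allele was the higher one in both lines, with B6 shares of 65.6% and 76.1% for Kdm5c and of 58.3% and 64.1% for Pbdc1.

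**Figure D1:**
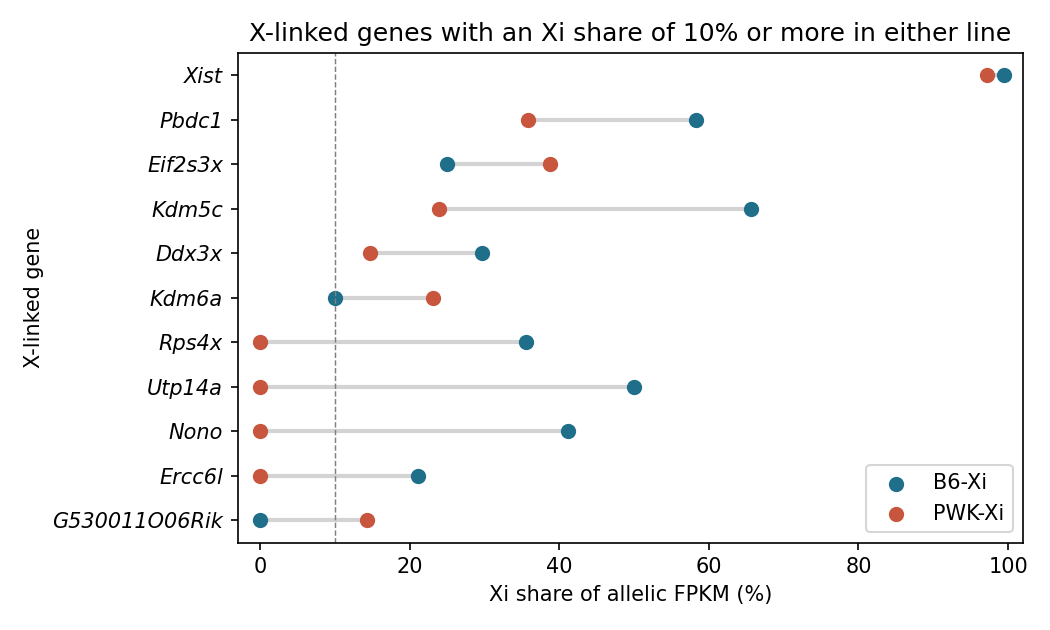
Xi share of allelic FPKM (%, horizontal axis) of the 11 X-linked genes at 10% or more in either line, with 1 point per line and gene and the 10% threshold dashed. Xist lies at 99.5% in B6-Xi and 97.2% in PWK-Xi, 5 known escape genes lie at or above 10% in both lines, and 5 genes reach 10% in 1 line only.

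Another 5 genes reached 10% in 1 line only. In B6-Xi these were Utp14a, a listed escape gene, at 50.0% of 8.91 FPKM, the RNA-binding protein gene Nono at 41.2% of 45.1 FPKM, Rps4x, and Ercc6l at 21.1% of 3.40 FPKM. Utp14a, Nono and Ercc6l had an Xi share of 0% in PWK-Xi. Reads of a gene wrongly assigned to B6 would also give an Xi share in B6-Xi and none in PWK-Xi. For these genes this cannot be told apart from expression from the Xi in 1 line. In PWK-Xi the only such gene was G530011O06Rik, at 14.3% of 10.4 FPKM against 0% in B6-Xi. Among genes with at least 5 FPKM in both lines, the largest increases in Xi share from B6-Xi to PWK-Xi after those of G530011O06Rik and Eif2s3x were those of Irak1 (0% and 4.46%), Ubqln2 (0% and 2.78%) and Bcap31 (0% and 2.68%). Shares moved in coarser steps in B6-Xi, so whether such small shares were present there too could not be told. Of the 11 escape genes measured, 5 passed in both lines, Utp14a passed in B6-Xi, and 5 passed in neither. Bgn, a matrix proteoglycan gene, had 665.4 and 483.1 FPKM with Xi shares of 0% and 0.0097%. Usp9x, Med14, Zfx and 1810030O07Rik had 0% in both lines at 3.14 to 12.1 FPKM. Of the genes of the X-inactivation centre, Xist and Rlim were measured in both lines, and Rlim, a ubiquitin ligase gene, had Xi shares of 0% and 0.069%. Tsix, which overlaps Xist in antisense, was listed at 0 in B6-Xi and had 33.2 FPKM, 50% from each allele, in PWK-Xi. The labels do not state that strand was kept, so its reads and those of Xist could not be told apart. Among loci of Xi architecture, 4933407K13Rik, the Dxz4 transcript, stayed at 0.219 and 0.594 FPKM, all from the active X.

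The autosomes served as the background for these shares. Their median B6 share was 50.0% in B6-Xi and 52.7% in PWK-Xi, but single chromosomes departed from it, and they were different ones in the 2 lines except for chromosome 16. In B6-Xi, chromosome 12 had a median B6 share of 0%, with 94.4% of its 234 genes at exactly 0. Chromosomes 10, 2 and 3 leaned to B6, with medians of 66.7%, 60.7% and 55.6%, and chromosomes 16, 11 and 4 leaned to PWK, with 33.3%, 40.7% and 42.9%. In PWK-Xi chromosome 1 had a median of 70.2%, chromosome 5 of 36.5% and chromosome 16 of 41.1%. The 10 remaining autosomes had medians between 46.2% and 53.8% in B6-Xi and between 50.6% and 54.5% in PWK-Xi.

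**Figure D2:**
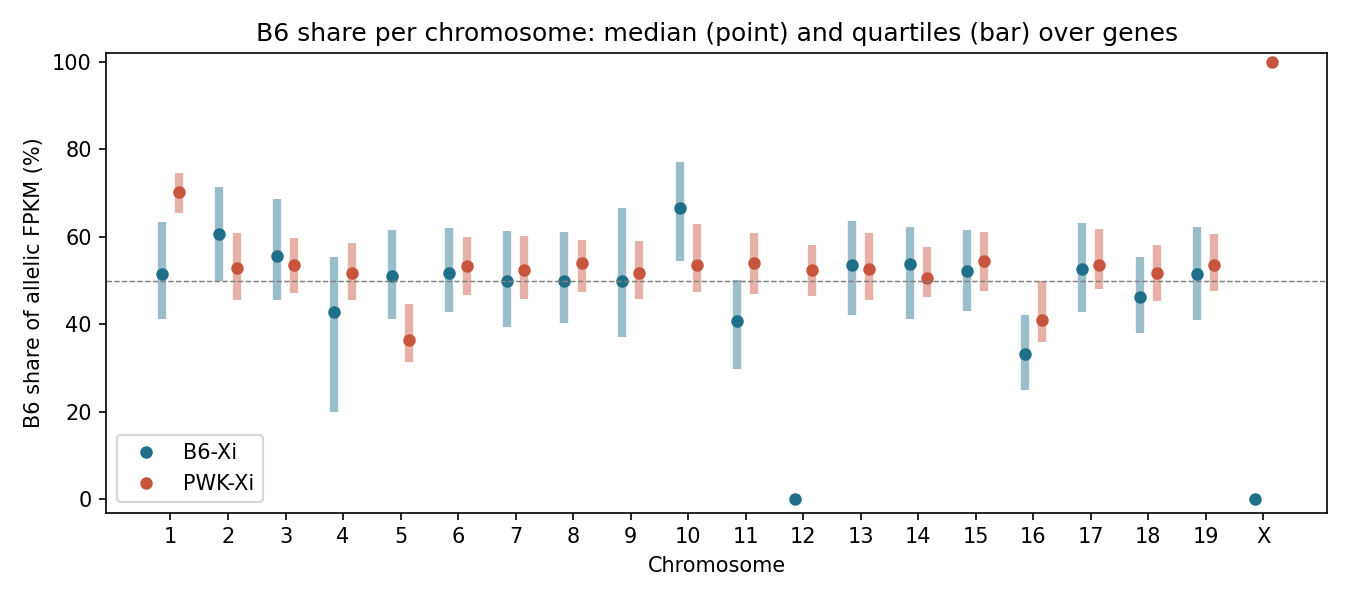
B6 share of allelic FPKM (%) per chromosome, with points for medians and bars for quartiles over genes with at least 1 FPKM in both lines. Chromosome 12 lies at 0% in B6-Xi, chromosome 1 at 70.2% and chromosome 5 at 36.5% in PWK-Xi, and the X at 0% and 100%.

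Several departures in B6-Xi had borders within a chromosome, while chromosomes 2 and 16 leaned over their whole length. On chromosome 12, the first 10 genes, from Rab10 to Atad2b, had B6 shares of 33.3% to 100%, and 223 of the 224 genes after them had 10% or less. Within chromosome 4, 97 consecutive genes with at least 1 FPKM in B6-Xi, from B4galt1 to Jun, had a B6 share of at most 10%, between the flanking genes Smu1 and Cyp2j6. The same part of chromosome 4 had a median of 51.9% in PWK-Xi. Outside chromosomes 4, 12 and X, no run of more than 4 genes with a B6 share of at most 10%, or of at least 90%, occurred in either line. In blocks of 20 genes, chromosome 9 of B6-Xi passed from a median of 66.7% (Alkbh8 to Uaca) to 46.5% (Tle3 to Ryk) and 37.2% (Srprb to Tgm4). The end of chromosome 3 lay at 72.3% (Hiat1 to Cyr61), the end of chromosome 11 lay at 19.3% (Mfsd11 to Sirt7), and chromosome 10 passed from 68.8% to 54.6% after Nap1l1. In PWK-Xi these parts had medians between 50.8% and 55.4%. Of 361 blocks, 57 in B6-Xi and 38 in PWK-Xi lay more than 15 points from the autosomal median, against at most 7 and 2 in 1000 shuffles of the gene order.

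**Figure D3:**
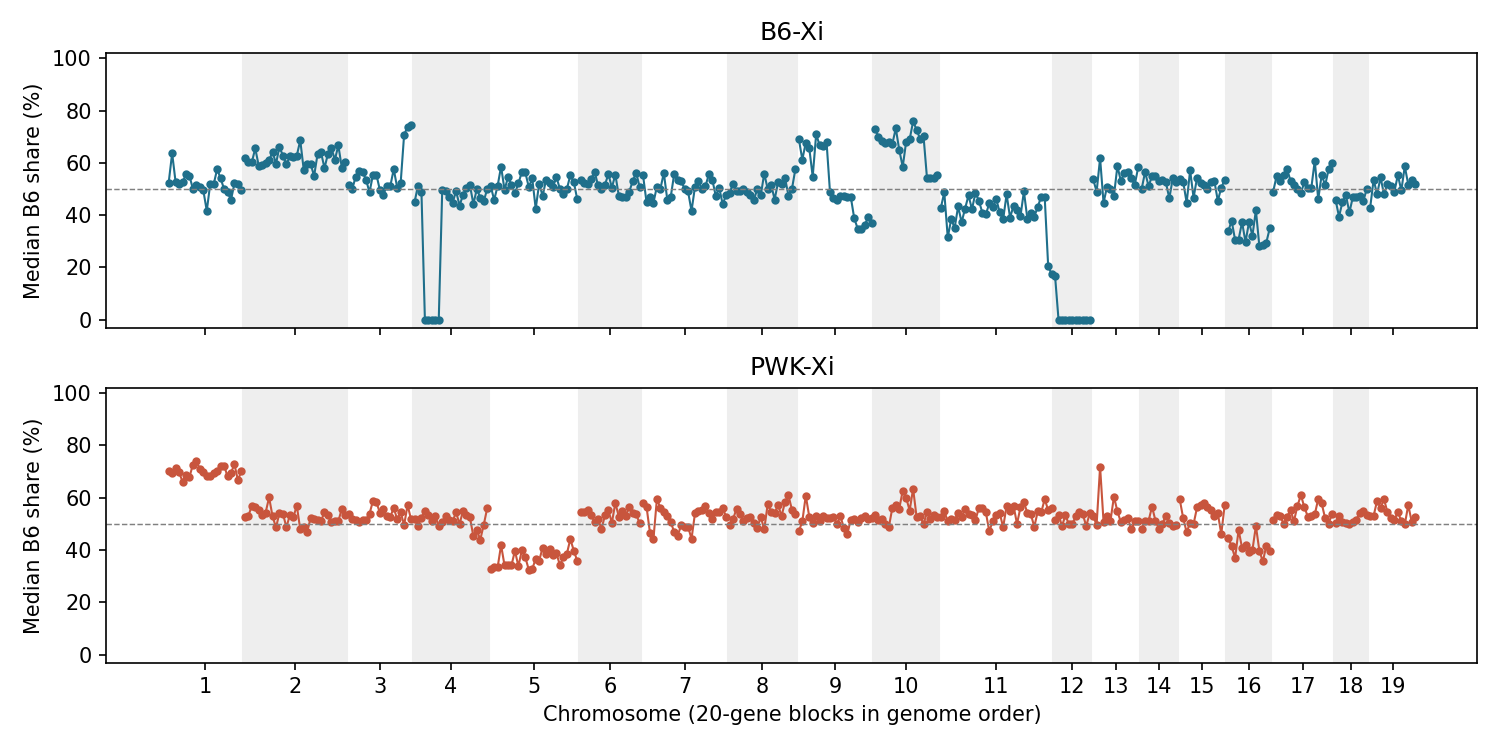
Median B6 share (%) of blocks of 20 consecutive genes in genome order, with chromosomes on alternating backgrounds. In B6-Xi the blocks reach 0% on part of chromosome 4 and most of chromosome 12 and step along chromosomes 3, 9, 10 and 11, while in PWK-Xi chromosomes 1 and 5 are shifted over their whole length.

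**Figure D4:**
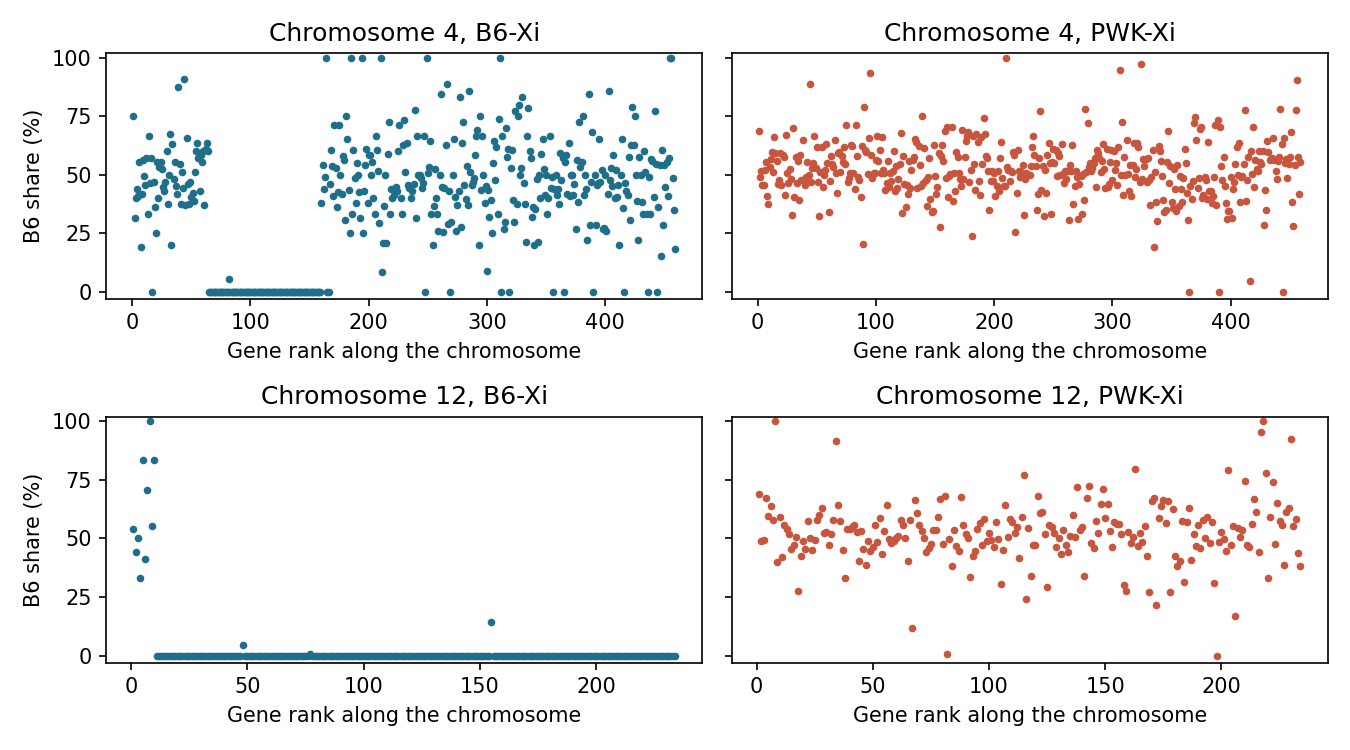
B6 share (%) of single genes by rank along chromosomes 4 (top) and 12 (bottom) in each line, for genes with at least 1 FPKM in both. In B6-Xi the B4galt1 to Jun part of chromosome 4 and all but the first 10 genes of chromosome 12 lie at or near 0%, and in PWK-Xi most genes show both alleles.

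Taken over whole chromosomes, total expression differed along with the shares of some and not of others. The median log2 difference (PWK-Xi over B6-Xi, relative to all autosomal genes above 0 in both lines) was 0.87 for chromosome 12, 0.41 for chromosomes 1 and 5, 0.28 for chromosome 16 and -0.45 for chromosome 11. It was between -0.23 and 0.01 for the 10 autosomes with no skewed median, and 0.07 for the X. Chromosomes 10, 3 and 2, which leaned to B6 in B6-Xi, lay close to that range when taken whole, at 0.11, 0.10 and 0.04. Inside chromosome 3, however, the end (Hiat1 to Cyr61) had 0.36 and the genes before it 0.06. Chromosome 10 had 0.16 up to Nap1l1 and -0.21 after it. The B4galt1 to Jun part of chromosome 4 had 0.80, and the rest of that chromosome -0.13. Along chromosome 9 the values were 0.57, 0.05 and -0.56 for its 3 parts, and the end of chromosome 11 had -1.10. Cdkn2a and Cdkn2b, cell cycle inhibitor genes within the chromosome 4 part, were listed at 0 in B6-Xi and had 6.88 and 14.7 FPKM, 53.8% and 50.8% from B6, in PWK-Xi. Of 5065 genes with at least 5 FPKM in PWK-Xi, 4.76% were listed at 0 in B6-Xi, so a 0 alone is not rare. Mtap, which lies beside this pair of genes and was chosen after its value was seen, had 51.1 FPKM in B6-Xi, all from PWK, and 21.6 FPKM in PWK-Xi.

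Of 3827 autosomal genes with at least 5 FPKM in both lines, 9 differed in B6 share by at least 80 points, 7 of them with the higher B6 share in PWK-Xi. Without the skewed chromosomes 3 such genes were left, and with a minimum of 1 FPKM there were 39. Of the genes named next, Crip2, Hspb1, H3f3a, Rab32, Xbp1, Trmt6, Rpl5 and Vasn lie on skewed chromosomes. The largest differences in that direction were those of Xbp1, an unfolded protein response factor gene, and Tmem115 (0% in B6-Xi and 100% in PWK-Xi), Hist1h2af (0% and 94.7%), Crip2 (0% and 92.5%) and the small heat shock protein gene Hspb1 (0% and 90.6%). In the other direction were H3f3a (100% and 0%), Rab32 (100% and 17.9%), Trmt6 (100% and 31.3%), Rpl5 (100% and 33.3%) and Vasn (100% and 34.6%). The histone genes and Rpl5 belong to families of near-identical copies, and their shares are uncertain. In both lines at least 90% came from B6 for 19 genes and from PWK for 18. All 5 B6 examples, Gm12191, Atp5g1, Igfbp6, Gm6251 and 2200002D01Rik, had 100% in both lines, and Hist1h2ah, Wfdc17, Hp1bp3, Thap7 and the mitotic kinase gene Plk1 had 0% in both.

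Imprinted genes, expressed from 1 parental copy, asked which strain gave which parental copy. The strain labels of the lines are written in opposite order, yet imprinted genes came from the same strain in both lines wherever they were monoallelic in both. Among paternally expressed genes, Sgce, a sarcoglycan gene, had a B6 share of 0% in both lines at 10.0 and 7.34 FPKM, Impact had 4.84% and 2.44%, and Peg3, under the 5 FPKM minimum, had 0% and 1.19%. Among maternally expressed genes, the growth factor receptor adaptor gene Grb10 had 100% in both lines, as had Igf2r and Cdkn1c, both under 5 FPKM. These genes under the minimum, and those of PWK-Xi alone, were named after their values were seen. At 5 FPKM, 3 of 7 measured members reached 90% from 1 strain in both lines, and at 1 FPKM 6 of 12 did, against 1.08% of all 7435 autosomal genes. Dlk1, on chromosome 12, had 0% and 16.9%. The maternally listed genes H13 (85.7% and 62.5%), Ube3a (42.9% and 43.1%) and Tssc4 (45.5% and 69.9%) had both alleles in both lines; Ube3a is imprinted mainly in neurons. In B6-Xi alone, at 1 FPKM and off chromosome 12, 4 of 6 paternally expressed genes were at least 90% PWK and 1 was at least 90% B6. Of 8 maternally expressed genes there, 3 were at least 90% B6. In PWK-Xi alone, where more of these genes were above 1 FPKM, 8 of 10 paternally expressed genes were at least 90% PWK and 8 of 12 maternally expressed genes at least 90% B6. They included Ndn (24.3 FPKM, 0% B6), Igf2 (2.98 FPKM, 0%), H19 (3.43 FPKM, 100%) and Meg3 (2.16 FPKM, 100%). Cd81 had 103.0 FPKM, 100% from B6. Like Ndn, Igf2, H19 and Meg3, it was listed at 0 in B6-Xi. Of 674 autosomal genes at 0 there and at 1 FPKM or more in PWK-Xi, 22.7% were at least 90% B6. Another 11.4% were at most 10% B6.

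The last comparison set total expression in PWK-Xi against B6-Xi. PWK-Xi had lower smooth-muscle-type contractile transcripts and higher transcripts of cholesterol synthesis and of single genes such as Apoe. Of 5490 genes with at least 5 FPKM in either line, 387 were at least 4-fold higher and 73 at least 4-fold lower in PWK-Xi. The 241 of these genes that were listed at 0 in B6-Xi fall among the 387 by construction, as do 8 listed at 0 in PWK-Xi among the 73; with genes above 0 in both lines only, 146 were higher and 65 lower of 5241. The median log2 difference of those 5241 genes was 0.19, and the log2 values below are given relative to it, while folds and counts by fold are without this shift.

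Contractile genes were lower in PWK-Xi. Of 7 measured, 6 were at least 2-fold lower and none at least 2-fold higher; the list's median log2 difference was -2.03, below all 10000 random lists. Of the 6, 2 lie on chromosomes with a skewed B6 share, and Tagln, Cnn1 and Tpm1 lie on chromosome 9, which has steps in B6-Xi but no skewed median and is not counted as skewed here or for the lists below. Whole chromosomes were counted, so genes outside the shifted parts of chromosomes 3 and 4 also count as lying on a skewed one. Those other parts had median B6 shares of 52.2% and 47.1% in B6-Xi. With 9 autosomes skewed and 10 not, genes of any list often lie on a skewed one, so these counts alone single out no list. Acta2, smooth muscle actin, went from 365.8 FPKM in B6-Xi to 15.03 FPKM in PWK-Xi, 22.9-fold lower, the largest decrease among genes above 0 in both lines with at least 20 FPKM in either. Myl9, a myosin light chain gene, had 108.5 and 12.1 FPKM, and Tpm1 and Tpm2, tropomyosin genes, had 398.1 and 129.0 FPKM and 76.5 and 20.7 FPKM. Tpm2 lies within the chromosome 4 part with almost no B6 expression in B6-Xi. Cald1 stayed close, at 159.8 and 150.5 FPKM. The other lowest genes in PWK-Xi included the G1 cyclin genes Ccnd1 (197.7 and 12.4 FPKM) and Ccnd2 (20.1 and 1.72 FPKM), Gas6, the ligand gene of TAM receptors (24.8 and 1.54 FPKM), Psmb8, an immunoproteasome gene (27.3 and 2.37 FPKM), and Tmem37 (111.7 and 8.79 FPKM). Ctla2a, Sncg, Klra18, Dclk1, Lgals9, Igfbp6 and Mgat4b completed the list, at log2 differences of -3.83 to -2.81, with Capzb, which had 59.9 FPKM in B6-Xi and was listed at 0 in PWK-Xi.

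Cholesterol synthesis genes were higher in PWK-Xi. Of 10 measured members above 0 in both lines, 6 were at least 2-fold higher and 4 lay within 2-fold; the median log2 difference was 1.02, above all 10000 random lists, and 3 of the 6 lie on chromosomes with a skewed B6 share. Fdps had 57.9 and 105.6 FPKM in B6-Xi and PWK-Xi, and Cyp51 had 15.1 and 42.6 FPKM. Among the other abundant members, Fdft1 was 1.9-fold and Sqle 1.45-fold higher in PWK-Xi, both within 2-fold. Insig1, a sterol-regulated membrane protein gene chosen after its value was seen, had 7.33 and 31.7 FPKM. Its increase was the largest of these 10 members. Idi1 was listed at 0 in B6-Xi and had 20.8 FPKM in PWK-Xi.

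By the fixed rule the 15 genes highest in PWK-Xi were, with 1 exception, listed at 0 in B6-Xi. They included Saa3, an acute-phase serum amyloid gene, at 3860 FPKM, the ribosomal protein genes Rpl10 (1076 FPKM) and Rps25 (508.9 FPKM), Ost4 (315.3 FPKM), Hmgn1 (231.6 FPKM), Dppa5a (134.9 FPKM), Cd81, Cox17 (102.8 FPKM) and Tdh (100.4 FPKM), with Mir682, Atp5c1, Polr2j, Hist1h2ad and Mlf2. The exception was Chchd10, a mitochondrial protein gene, with 0.492 and 345.5 FPKM. The ribosomal protein genes are used by all cells, so these values of 0 cannot be read as absence. Genes above 0 in both lines, chosen after their values were seen, gave Il1rl1, the interleukin 33 receptor gene (4.23 and 150.7 FPKM), the apolipoprotein gene Apoe (12.6 and 339.9 FPKM), the matrix genes Tnc (4.50 and 119.9 FPKM), which lies within the chromosome 4 part with almost no B6 expression in B6-Xi, and Mmp3 (13.9 and 233.2 FPKM), Crabp1 (82.7 and 1286 FPKM) and Fabp3 (1.11 and 73.6 FPKM).

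**Figure D5:**
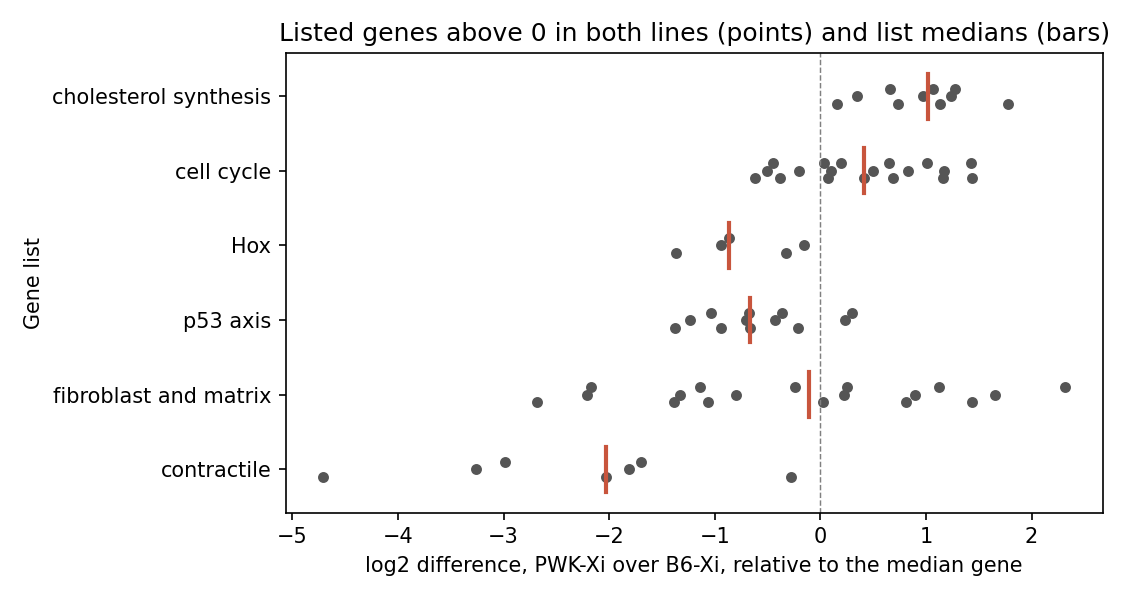
Log2 difference between the lines (PWK-Xi over B6-Xi, relative to the median gene, horizontal axis) of the members of 6 gene lists that were above 0 in both lines, with a bar at each list's median. Contractile genes have a median of -2.03 and cholesterol synthesis genes of 1.02, while fibroblast and matrix genes spread to both sides of 0.

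Fibroblast and matrix genes went both ways. Of 18 measured above 0 in both lines, 6 were at least 2-fold higher and 5 at least 2-fold lower in PWK-Xi, and 5 of the former and 5 of the latter lie on chromosomes with a skewed B6 share. The list had a median log2 difference of -0.11 at percentile 37.7. S100a4, a calcium-binding protein gene, had 13006 FPKM in B6-Xi and 2321 FPKM in PWK-Xi, Sparc had 579.5 and 252.4 FPKM, and Dcn, the decorin gene, had 79.1 and 456.4 FPKM. Cell cycle genes had a median of 0.41 at percentile 98.9, with 6 of 19 at least 2-fold higher and none lower, among them Pcna (60.02 and 139.9 FPKM) and Rrm2 (22.8 and 73.0 FPKM). Of these 6 genes, 5 lie on chromosomes with a skewed B6 share, and Rrm2 lies on the part of chromosome 12 with almost no B6 expression in B6-Xi. Genes of the p53 axis had a median of -0.67 at percentile 0.47. Cdkn1a had 187.3 and 133.9 FPKM, Ccng1 97.4 and 53.9 FPKM, and 10 of 12 lay within 2-fold. Cdkn2a and Cdkn2b, listed at 0 in B6-Xi, were higher in PWK-Xi. With them included and no shift removed, the median of the p53 axis was -0.35 at percentile 0.91. Hox genes had a median of -0.86 over 5 members at percentile 0.675, led by Hoxc8 (26.9 and 11.4 FPKM), and 4 lay within 2-fold. Hoxa10, chosen after its value was seen, went the other way, listed at 0 in B6-Xi and at 5.28 FPKM in PWK-Xi. With Hoxa10 included and no shift removed, the Hox median was -0.40 at percentile 2.96. Under 5 FPKM in both lines, Hoxa5, Hoxa9, Hoxa11, Hoxc10 and Hoxd9 were also higher in PWK-Xi. Hoxb2, Hoxd4 and Hoxd8 were lower there. Only 4 interferon response genes were measured, with a median of -1.56 at percentile 0.17; these included Psmb8 and Ifi35 (21.4 and 8.41 FPKM). Of the 3 at least 2-fold lower, 2 lie on chromosomes with a skewed B6 share, and the median (-1.36 with no shift removed) was -0.69 with a minimum of 1 FPKM and 0.20, in the other direction, with no filter. Housekeeping genes had a median of -0.50 over 15 members at percentile 19.4, with Eef1a1 at 3051 and 1878 FPKM and Actb at 2625 and 1518 FPKM. The imprinted lists had medians of -0.39 (3 paternally expressed members) and 0.43 (5 maternally expressed members), at percentiles 16.4 and 86.6. With members at 0 in 1 line included, as planned, and no shift removed, the medians were 0.48 and 0.69, at percentiles 75.8 and 91.7, so the direction of the paternally expressed list depended on 1 such member.

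Markers of other cell types were low, with a few exceptions. The highest endothelial marker reached 0.123 FPKM in either line, the highest muscle marker 0.010 FPKM, the highest epithelial marker 2.68 FPKM (Krt19 in B6-Xi) and the highest immune marker 3.25 FPKM (Cd68 in PWK-Xi). The highest neural marker was Tubb3 at 2.91 and 5.32 FPKM, and of the adipocyte markers Fabp4 had 108.3 and 54.9 FPKM while Pparg stayed at 0.872 and 0.655 FPKM. Pluripotency genes were listed at 0 in B6-Xi. In PWK-Xi the pluripotency factor gene Pou5f1 had 15.1 FPKM and Sox2 2.19 FPKM, both 100% from B6, and Nanog, Dppa4 and Esrrb stayed between 0.179 and 0.360 FPKM.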

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

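The tests of the chromosome and imprinting patterns below were chosen after the results were seen, and those of the pluripotency transcripts were written before the values they use. Among the X-linked, autosomal and imprinted genes named in the report for their allelic shares, 12 leaned to opposite sides of 50% in the 2 lines by at least 5 points; other genes were not screened for this, and with 1 library per line none of these differences was tested. As Xi share in PWK-Xi minus B6-Xi, the difference was -41.7 points for Kdm5c and -22.5 points for Pbdc1, which had the higher Xi allele in B6-Xi and the higher active allele in PWK-Xi. For both genes the B6 allele was the higher one in both lines, at 65.6% and 76.1% for Kdm5c and 58.3% and 64.1% for Pbdc1. The strain of the higher allele thus did not change. As B6 share in PWK-Xi minus B6-Xi, it was -100 points for H3f3a, -82.1 for Rab32, -68.7 for Trmt6, -66.7 for Rpl5 and -65.4 for Vasn. In the other direction it was 100 points for Xbp1, 100 for Tmem115, 94.7 for Hist1h2af, 92.5 for Crip2 and 90.6 for Hspb1. All of these autosomal genes were named for the largest B6 share differences, so their opposite lean largely follows from that choice. Crip2 lies on the part of chromosome 12 that had almost no B6 expression in B6-Xi.

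Whole chromosomes and chromosome parts leaned to 1 strain, most of them in 1 line only. A bias in allele assignment would act on both lines alike, and for the 8 skewed chromosomes other than 16 the other line's median lay at most 1.40 points from its autosomal median, which argues against it; for chromosome 16, which lay -11.6 points from the autosomal median even in the line where it was nearer, it cannot be told apart from unequal copies, since both lines lean the same way. Unequal copy number may account for chromosome 12, whose total expression differed by 0.87 on the log2 scale against -0.23 to 0.01 for the unskewed chromosomes. It may account too for parts of chromosomes 3, 9, 10 and 11, where expression changed by at least 0.30 at each of the 5 steps in B6 share. Between the front and rear part of any of 9 chromosomes with neither skew nor step, expression changed by at most 0.26. Smaller stretches of such chromosomes varied more. On chromosome 13, the 2 blocks from Hist1h2af to Pxdc1 lay at -0.94 and -0.99 and the next block at 0.19. Comparing front and rear parts therefore cannot separate the smaller steps from variation along a chromosome. Unequal copy number may also account for the B4galt1 to Jun part of chromosome 4, where expression differed from the rest of the chromosome by 0.93. Of the other 7 skewed chromosomes, taken whole, 4 (1, 5, 11 and 16) lay outside the unskewed range by more than 0.1. Chromosomes 2, 3 and 10 did not, so for these 7 as a set a change of whole chromosomes stays open. On chromosome 3, however, the genes before Hiat1 had a median B6 share of 52.2% in B6-Xi and a difference of 0.06. Its lean was thus that of its end and not of the whole chromosome. Chromosome 10 had 68.8% up to Nap1l1 and 54.6% after it. No DNA measurement was analysed here, and no biological explanation beyond copy number was tested.

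Imprinted genes came from the same strain in both lines, although the lines are labelled as reciprocal. Of 11 members measured at 1 FPKM and off chromosome 12, 54.5% came at 90% or more from the strain of their list in both lines, PWK for paternally and B6 for maternally expressed genes, and none swapped. A strain difference at each gene would not sort by list, yet 100% of the 6 members at 90% or more did; Nnat, paternally expressed but under 1 FPKM in PWK-Xi and so not counted, had 100% B6 in both lines. A candidate explanation is that both lines had a B6 mother and a PWK father, with the order of strains in the labels carrying another meaning, such as which X is inactive. The pedigree is not stated in the sources used here, and 6 genes are few.

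Pluripotency transcripts from the B6 allele stood out in PWK-Xi, with Pou5f1 and Sox2 at 100% B6; Dppa5a and Tdh, abundant in embryonic stem cells, were at 99.8% and 100% B6. Of other stem cell genes listed before their values were seen, 6 reached 1 FPKM in PWK-Xi, and 50% of these had a B6 share of 90% or more, so RNA from B6 stem cells cannot be told apart from another source; the median B6 share of the 6 was 77.0%, which leaves reactivation of both alleles in the hybrid cells open too. Utf1 (5.80 FPKM, 61.8% B6), Zfp296 (4.60 FPKM, 2.88% B6) and Tdgf1 (1.48 FPKM, 46.2% B6) were not B6-only, and Lefty1, 1 of the 3 at 90% or more, was at 100% B6 in B6-Xi too, with 4.08 FPKM; without it the count was 2 of 5, under the 50% set beforehand as the lower bound. Oocyte RNA was argued against by 2 of 14 oocyte genes at 1 FPKM or more, under the 3 set beforehand. These 2, Khdc3 and Ooep, had B6 shares of 100% and 97.0% in PWK-Xi and so shared the B6-only pattern. Genes listed at 0 weigh little by themselves, but 4 oocyte genes were above 0, at no more than 1.44 FPKM. Of 19 housekeeping genes, 3 were listed at 0. The labels name no such cells. B6-only expression was not rare among genes listed at 0 in B6-Xi. Of 674 such autosomal genes at 1 FPKM or more in PWK-Xi, 22.7% had a B6 share of at least 90%. PWK-only expression was rarer, with 11.4% at a B6 share of at most 10%. RNA from a B6 source would itself raise the 22.7%, so that value is not an independent background.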

How the results depend on the processing

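Alternatives with skewed chromosomes, B6-only genes or genes at 0 left out were chosen after the data were seen; the others were planned. No paired analysis was possible because each group holds 1 library. Of the values that answer a comparison, 125 were unchanged under an alternative, 26 moved and 1 reversed; the causes were not tested except where the alternative's construction shows them. The median autosomal B6 share was unchanged throughout, as were the contractile, cholesterol synthesis and cell cycle medians. Rescaling the alleles changed nothing in B6-Xi, whose autosomal median was already 50%.

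A pseudocount of 1 FPKM per allele pulls low genes toward 50% by construction: it raised the median Xi share to 13.02% in B6-Xi and 11.5% in PWK-Xi, the genes at 10% in both lines from 6 to 119 and in 1 line from 5 to 42, and cut same-strain autosomal genes from 37 to 18 and imprinted ones from 3 to 1. Pooled FPKM gave an Xi share of 8.93% in B6-Xi, mostly through Rps4x. Genes at 10% in both lines numbered 10 with no minimum and 3 at a threshold of 25%; those in 1 line numbered 3 and 2 with minimums of 5 and 10 FPKM. With a minimum of 1 FPKM, genes differing by 80 points rose from 9 to 39, same-strain genes to 80 and imprinted ones to 6; with 10 FPKM the last pair of counts was 23 and 1. Without skewed chromosomes 3 genes differed by 80 points.

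Between the lines, a pseudocount of 5 FPKM left 112 genes higher and 23 lower in PWK-Xi by 4-fold, from 387 and 73. Genes above 0 in both lines gave 146 higher, and leaving out skewed chromosomes gave 175 and 41, in part because fewer genes entered. The fibroblast median (0.22 with no shift removed) was -0.33 without skewed chromosomes, and that of paternally expressed imprinted genes (0.48) was -0.19 among genes above 0 and 1.14 without skewed chromosomes. The interferon median (-1.36 over 4 genes) was -0.69 with a minimum of 1 FPKM and reversed to 0.20 with no filter, which adds members near 0. Of values for single named genes, 269 were unchanged and 57 moved, none reversing. Depth is unknown, and the coarser steps of the shares in B6-Xi limit the precision of single genes there.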

Other observations

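Genes used to name other embryonic lineages, on lists written after the main results but before their own values were seen, were low in both lines. Of 8 trophoblast genes, Gata3 alone reached 1 FPKM, at 4.16 FPKM in B6-Xi and 6.16 FPKM in PWK-Xi with B6 shares of 27.8% and 21.8%. None of 7 primitive endoderm genes reached 1 FPKM in either line. Lefty1, a stem cell list member, was the only one at 1 FPKM in B6-Xi, with 4.08 FPKM, and had 1.13 FPKM in PWK-Xi, 100% from B6 in both.

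Several genes had a similar uneven share in both lines without being imprinted list members. Pkm, a glycolytic enzyme gene, had B6 shares of 86.7% in B6-Xi and 76.2% in PWK-Xi, Tpi1 had 67.4% and 67.4%, Thy1 had 86.7% and 84.7%, Fabp4 had 10.4% and 6.73%, and Eno1 had 0% and 4.76%. These genes were chosen after their values were seen. Pkm and Thy1 lie on chromosome 9, part of which leaned to B6 in B6-Xi. Eno1 and Tpi1 have processed copies elsewhere in the genome, and reads of copies were not separable here.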
